A study of Homo sapiens with 4 samples.

How the data were processed

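Total RNA from a tet-on mouse p53 line of H1299 cells, grown in medium with 10% serum, was labelled with biotin as single-stranded cDNA and hybridised to a whole-transcript Affymetrix gene array, per the labels' protocols. Each array gave 1 value per probe set. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA; versions, settings, genome build and filters are not given in the sources used here. The deposited values are log2 expression levels rounded to 2 decimals, between 2.26 and 14.3 on the 4 arrays, with medians of 7.26 to 7.33. RMA corrects background, makes the arrays' intensity distributions equal and summarises the probes of a set, so a change of all transcripts together would be hidden, and fold changes of dim genes are compressed. Scanner files were not used here, so the background correction could not be varied, and no detection call per probe set was used.

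The table held 33297 rows. The platform annotation gave 1 gene symbol for 19460 rows, several for 1754 and none for 12083; a row with several was never named. Gene IDs of 19429 of the 19460 rows were found in the RefSeq gene table of GRCh38.p14, which served for names and gene order only; no coordinates are given because the array's build was not stated. A gene was represented by the probe set with the highest mean over the 4 arrays, which left 18417 genes, 769 of them with over 1 probe set; probe sets of 4 of these were called in opposite directions. Of 395 list entries fixed before the data were examined, 344 were measured; the rest, among them all mitochondrially encoded genes, were not analysed here. A planned check is not reported here.

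Groups and replicate numbers came from the sample titles. limma 3.58.1 in R 4.3.3 was used to fit induced against uninduced arrays (lmFit, eBayes with a constant prior, no covariate, 2 residual and 7.20 total degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05, and at 2-fold with an absolute log2 fold change of at least 1. SEs are limma's moderated ones (median 0.092). The labels call the replicates technical and do not say whether they share an RNA extract, so the test compares these arrays, not independent cultures. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 24 lists, with an estimated correlation and limma's fry test beside it, and each list's median was ranked among 10000 random lists matched in 20 bins of mean level. The lists covered p53 targets in growth arrest, apoptosis, feedback, DNA repair, metabolism, membrane and secreted genes and noncoding RNA; G1/S, G2/M and histone genes; amino acid response, endoplasmic reticulum stress, interferon, NF-kB, NRF2, sterol, glycolysis, mesenchymal, ribosome biogenesis, immediate early and housekeeping genes; and markers of blood, fibroblast or endothelial and lung epithelial cells.

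The genes named were chosen by a rule also set before the data were examined: MDM2 and CDKN1A among genes always named; the 10 largest rises and 10 largest falls among called genes whose groups did not overlap; and the 4 members with the largest absolute change of each p53, G1/S and G2/M list and the 2 of each other list. Other list members named, such as BAX, FAS, BBC3, PTTG1, CDK1, PCNA, IDI1, POLR1A and GAPDH, and every gene named only in the closing section, were chosen after their values were seen.

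Data were simulated with the real genes' mean levels, spreads drawn at random from limma's fitted prior, and independent normal noise. There the fit recovered 46.3% of 67 genes changed 1.5-fold, 94.0% of 67 changed 2-fold and 98.5% of 66 changed 4-fold. It called 6 of 18217 unchanged genes. The noise followed limma's own model, and far fewer genes were changed than were called in the real data. These rates therefore do not describe the real comparison. The alternatives tried were quantile normalization again, centring each array on its median, leaving out probe sets under the 40th percentile of mean level, averaging a gene's probe sets, all rows of the table, an intensity trend with a robust prior, limma's treat against a fold of 1.2, the replicate number as a block, leaving out each array, and camera's estimated correlation. Random shuffles and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.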

Results

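Gene expression was measured with a whole-transcript Affymetrix array in H1299, a human non-small cell lung carcinoma line that lacks p53, carrying a stable tet-on construct for mouse p53. The study compared the line before induction with the same line after 24 hours in 0.5 µg/mL doxycycline, the drug that switches the construct on. The comparison addresses which transcripts differ once p53 is expressed in cells that otherwise lack it. There were 4 arrays, 2 uninduced and 2 induced, and the labels call the 2 arrays of each group technical replicates. The p-values below therefore measure only the spread between arrays, and the number of arrays limits the precision. No sample received doxycycline without the construct, so every difference is between induced and uninduced cells of the construct line. The 2 arrays of a group correlated across genes at r = 0.997 when uninduced and r = 0.995 when induced, against 0.917 to 0.921 between the groups (genes are not independent replicates). The median SD between the 2 arrays of a group was 0.057 log2 units uninduced and 0.085 induced.

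CDKN1A (probe set 8119088), the p21 inhibitor of cyclin-dependent kinases, rose 10.8-fold, from 9.14 ± 0.035 to 12.57 ± 0.092 log2 units (SD, n = 2 arrays each). MDM2 (probe set 7956989), the ubiquitin ligase that degrades p53, rose 7.39-fold, from 9.85 ± 0.0071 to 12.73 ± 0.042. The largest measured rise was that of CRYAB (probe set 7951662), the small heat shock protein αB-crystallin, at 74.3-fold (log2 fold change 6.21, SE 0.10). FLJ36000 rose 43.1-fold, CLCA2, a regulator of chloride conductance, 35.8-fold and PDE3A, a cyclic nucleotide phosphodiesterase, 24.3-fold. CCDC39 and DNAI3, both genes of ciliary axonemes, rose 24.2-fold and 19.6-fold. GDF9, CRISPLD2, the adhesion receptor gene ADGRG1 and the lysosomal membrane gene LAMP3 rose 23.2-fold, 22.5-fold, 22.2-fold and 19.1-fold. Of these 10 genes, 7 (CRYAB, CLCA2, PDE3A, CCDC39, DNAI3, GDF9 and CRISPLD2) had uninduced levels under 6.26 log2 units. That is the median of 20 blood, fibroblast and endothelial markers on the uninduced arrays. The folds and order of these 7 genes therefore depend on the background level of the array. The same limit holds for other genes named below that start under that level, such as TRIM22 (5.035), MIR34A (5.115), ANKRA2 (5.78) and IFIT3 (5.84). The 10 largest falls were led by NUF2 (probe set 7906930), a kinetochore protein, which fell by 3.98 on the log2 scale (SE 0.13), ASPM, a spindle pole protein, which fell by 3.96 (SE 0.14), and TTK, the spindle checkpoint kinase, which fell by 3.91 (SE 0.12). The other falls were those of the kinetochore and centromere genes CENPI, CENPK and NDC80, with log2 fold changes of -3.83, -3.70 and -3.62, the recombination genes XRCC2 and RAD51AP1 (-3.79 and -3.73), DTL, which controls replication licensing (-3.69), and DEPDC1 (-3.82).

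Of 18417 genes tested, 8311 (45.1%) differed between induced and uninduced arrays with limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05, 3789 higher and 4522 lower after induction. At least 2-fold changes were called for 2439 genes, 1193 higher and 1246 lower, and 4-fold changes for 275 higher and 243 lower. Which direction held more genes depended on the scaling, since the higher share of all calls was 45.6% as deposited and 50.2% after quantile normalization again, and that of 2-fold calls 48.9% and 52.9%. CDKN1A, MDM2, the 10 largest rises and the 10 largest falls had adjusted p-values between 4.5e-07 and 2.2e-06 in limma's test. The number of genes past the threshold fell to 5043 without uninduced array 1, 4959 without uninduced array 2, 6765 without induced array 1 and 6904 without induced array 2, whereas the count of 2-fold changes stayed between 2392 and 2519 whichever array was left out. The 10 largest falls ended at induced levels of 5.84 to 7.42 log2 units, where the same 20 marker genes had a median of 6.34; no detection call was used here to set a lower limit of measurement.

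**Figure D1:**
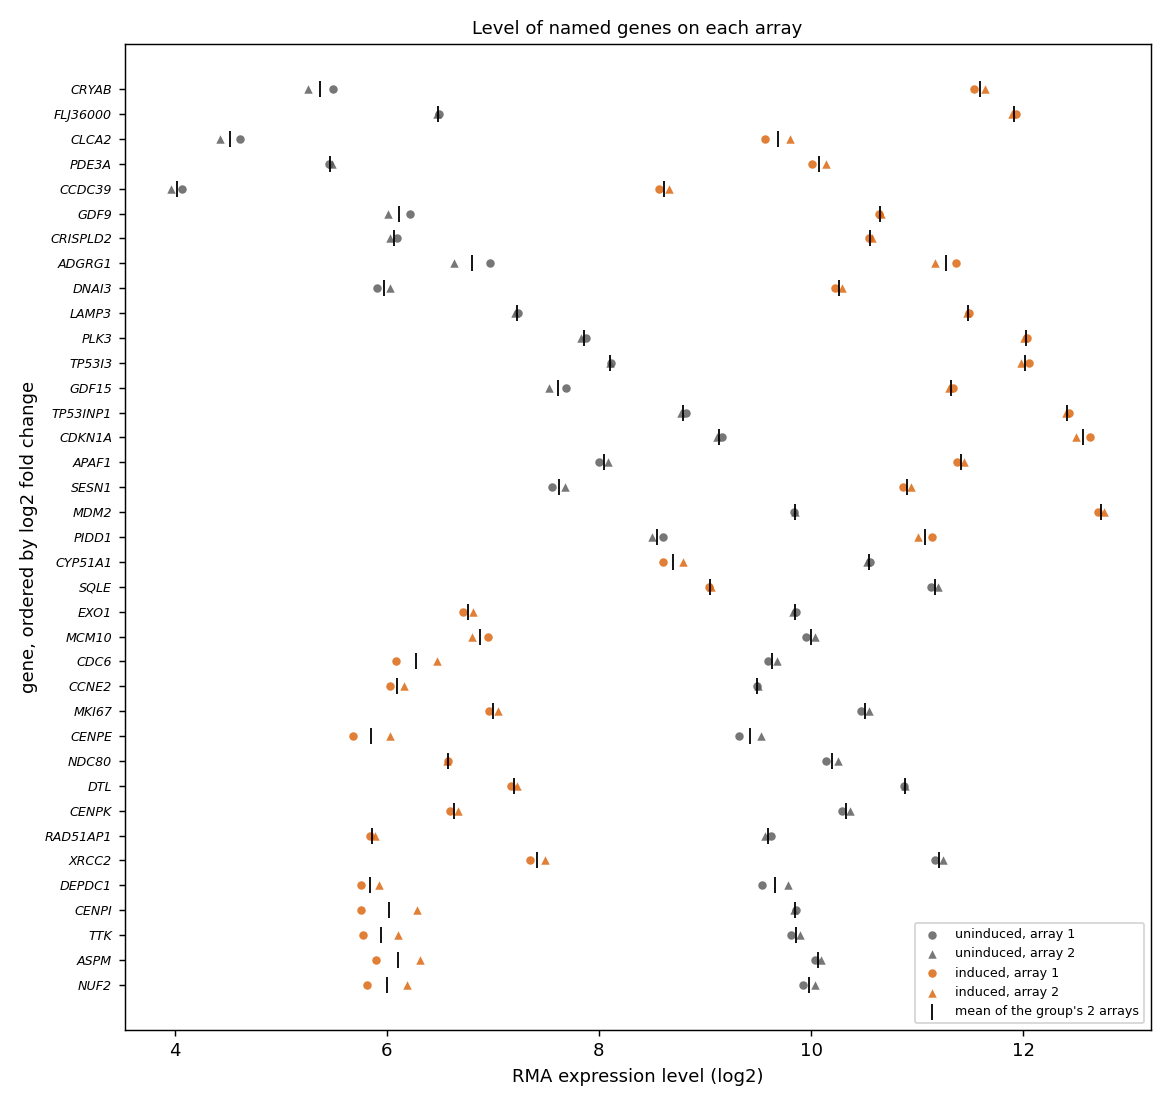
RMA expression level (log2, horizontal axis) of 37 named genes on each of the 4 arrays, ordered by log2 fold change; circles and triangles are arrays 1 and 2 of the uninduced (grey) and induced (orange) groups, and black ticks are the means of 2 arrays. The 2 arrays of a group lie close together, and the groups are apart for each of the 19 genes that rose and the 18 that fell. The separation follows in part from the choice of genes. The largest rises and falls were taken from genes whose groups did not overlap, and most others for their large change. Over all genes tested, the groups were apart for 66.8%, against 33.3% by chance with 2 arrays against 2.

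Genes known as direct targets of p53 were taken in 6 coding lists and 1 noncoding list fixed before the data were examined. Growth arrest genes rose almost throughout: of 12 measured, 11 rose and 1, CABLES1, fell (the same counts when adjusted over the list alone), with a median log2 fold change of 1.67. PLK3, a stress-activated kinase, rose by 4.17 on the log2 scale, the secreted growth factor GDF15 13.1-fold and SESN1, an inhibitor of mTORC1 signalling, 9.75-fold, beside CDKN1A. Of 17 apoptosis genes, 13 rose, 1 fell and 3 did not pass the test (14 rose and 1 fell when adjusted over the list alone), with a median of 1.13. TP53I3, a quinone oxidoreductase, rose 15.0-fold, TP53INP1 12.3-fold, APAF1, the core of the apoptosome, 10.3-fold and PIDD1, the scaffold of the PIDDosome, 5.76-fold. The death receptor genes FAS and TNFRSF10B rose 2.19-fold and 2.46-fold and BAX 1.89-fold. BBC3, which encodes PUMA, had a log2 fold change of 0.35 (SE 0.13, adjusted p = 0.0581) and AEN one of 0.19 (SE 0.089, adjusted p = 0.131) in limma's test. STEAP3, a ferrireductase gene of the same list, fell by 1.66 (SE 0.096).

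Feedback regulators of p53 also rose for the most part, 8 of 10 with 1 lower and 1 not past the test (8 and 1 when adjusted over the list alone). TP53INP1, MDM2 and ZMAT3, an RNA-binding protein gene that rose 5.72-fold, led that list, followed by TRIM22 at 2.85-fold. Of 9 DNA repair and nucleotide supply genes, 6 rose and 2 fell (the same when adjusted over the list alone). RRM2B, the p53-inducible ribonucleotide reductase subunit, rose 4.53-fold, the translesion polymerase gene POLH 4.29-fold, GADD45A 2.93-fold and XPC, the damage sensor of nucleotide excision repair, 2.73-fold, whereas FANCC fell by 1.03 (SE 0.15) and POLK fell by 0.41 (SE 0.11). Metabolic and autophagy genes rose in 10 of 14 and fell in 0 (the same when adjusted over the list alone), among them SUSD6 at 7.44-fold, PANK1, a pantothenate kinase, at 5.76-fold, the ceramidase gene ACER2 at 5.37-fold and TIGAR, a fructose bisphosphatase, at 4.53-fold. Membrane, secreted and other targets rose in 25 of 29 and fell in 1 (25 and 1 when adjusted over the list alone). ANKRA2 rose 12.7-fold, ABHD4 10.3-fold, TMEM63B 6.06-fold and CYFIP2 5.17-fold, whereas THBS1, the gene of a matrix thrombospondin, fell by 1.92 (SE 0.082). Of 3 noncoding genes measured, TP53TG1 rose 3.64-fold and MIR34A 2.37-fold, while MIR22HG had a log2 fold change of 0.25 (SE 0.091, adjusted p = 0.0644 in limma's test, though all 3 passed when adjusted over the list alone).

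Set against all other genes by limma's camera test with a preset correlation of 0.01, each p53 list shifted upward, with adjusted p-values of 9.4e-07 for growth arrest, 9.4e-07 for apoptosis, 0.000233 for feedback, 0.00793 for DNA repair, 5.3e-06 for metabolism, 1.7e-10 for membrane and secreted genes and 0.0227 for noncoding RNA. With an estimated correlation, which leaves 2 residual degrees of freedom, none of these calls held: adjusted p = 0.153 with an estimated correlation for growth arrest, apoptosis, metabolism and membrane genes, 0.185 for feedback, 0.239 for DNA repair and 0.272 for noncoding RNA. The noncoding call also ended without dim probe sets (adjusted p = 0.123) and without induced array 2 (0.0587). limma's fry test, which asks whether the genes of a list move on balance in 1 direction, gave adjusted p-values from 0.000583 to 0.00155 for these lists. The medians of the coding lists lay at or above the 99.89th percentile of 10000 random lists matched on mean level.

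Cell cycle genes moved the other way. Of 29 G2/M and mitosis genes, 28 fell and 0 rose (the same when adjusted over the list alone), 27 of them at least 2-fold, with a median log2 fold change of -2.73. ASPM and TTK were followed by the mitotic kinesin gene CENPE, which fell by 3.57 (SE 0.13), and the proliferation marker MKI67, which fell by 3.51 (SE 0.087). CDK1, the mitotic kinase, fell by 3.45 (SE 0.12) and its partner CCNB1 fell by 2.69 (SE 0.086). PTTG1, the securin gene, had a log2 fold change of -0.12 (SE 0.092, adjusted p = 0.355 in limma's test). Of 26 G1/S and DNA replication genes, 24 fell and 2 rose (the same when adjusted over the list alone), 22 falling at least 2-fold, with a median of -2.14. CCNE2, which encodes cyclin E2, fell by 3.40 (SE 0.088). The log2 fold changes of the replication origin genes CDC6 and MCM10 were -3.36 and -3.12, that of the exonuclease gene EXO1 was -3.08 and that of RRM2, the S-phase ribonucleotide reductase subunit, was -3.03. The 2 that rose were PCNA, the replication clamp, at 1.51-fold, and RRM1 at 1.33-fold. Replication-dependent histone genes fell in 11 of 14, with 3 not past the test (12 fell and 1, H2BC21, rose when adjusted over the list alone). H3C2 fell by 2.53 (SE 0.083) and H3C8 fell by 2.30 (SE 0.11), values that are uncertain because near-identical histone copies can share probes. Camera gave adjusted p-values of 8.3e-19 for G2/M, 2.9e-12 for G1/S and 1.0e-05 for histones. None of these held with an estimated correlation, where adjusted p = 0.202 with an estimated correlation for G2/M, 0.153 for G1/S and 0.153 for histones. Fry's adjusted p-values for the same lists lay between 0.000583 and 0.00112.

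**Figure D2:**
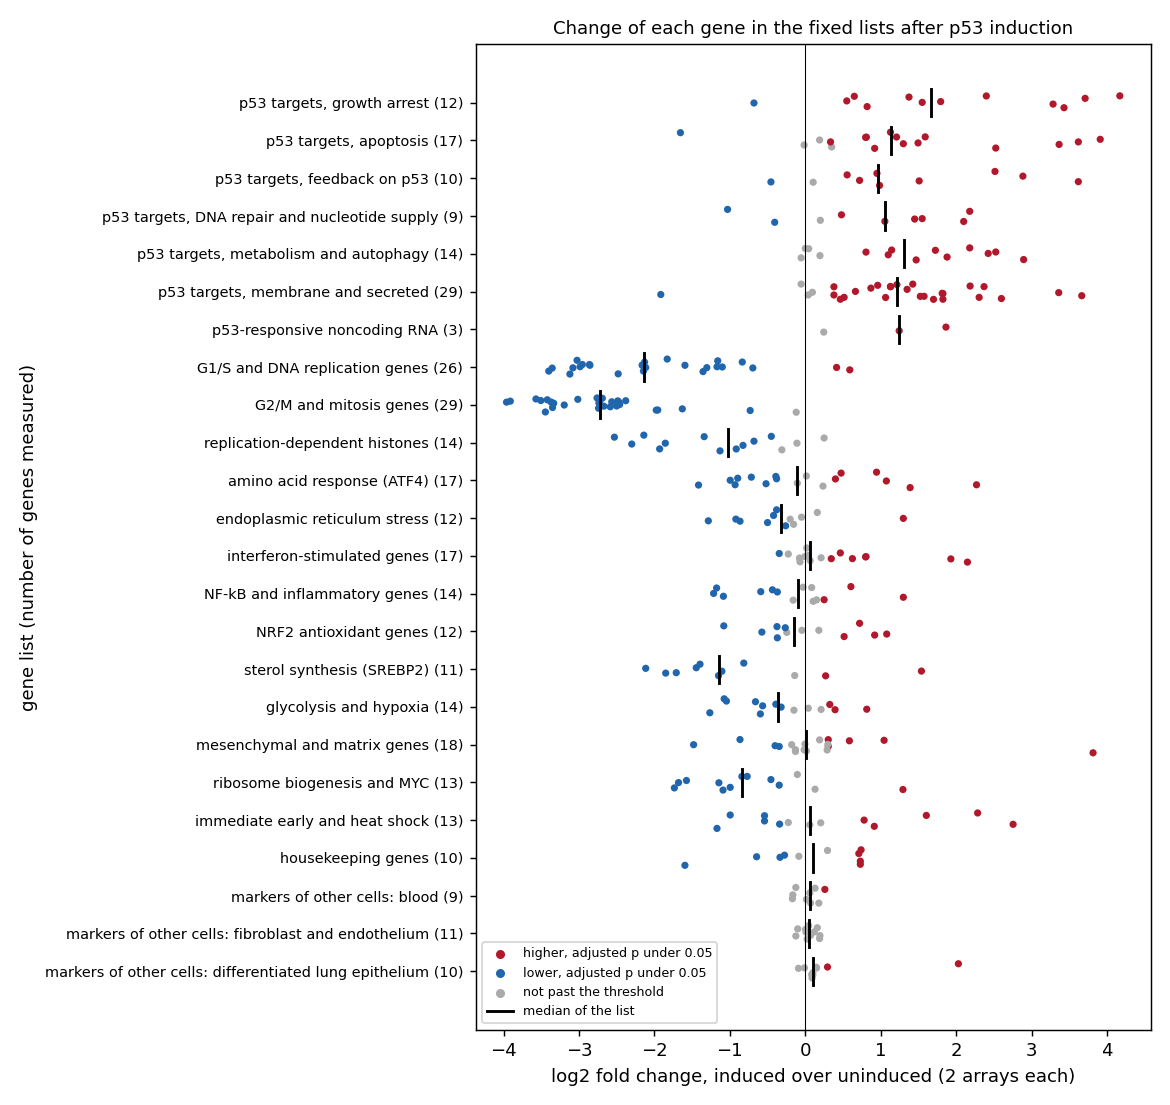
Log2 fold change, induced over uninduced (horizontal axis, means of 2 arrays each), of every measured gene in 24 fixed lists; each point is a gene, coloured by limma's adjusted p and direction, and the black bar is the list's median. The p53 target lists lie mostly to the right of 0, with medians from 0.97 to 1.67, and the G1/S and G2/M lists to the left, with medians of -2.14 and -2.73.

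Most genes of sterol synthesis fell. Of 11 measured, 8 fell, 7 of them at least 2-fold, and 2 rose (the same when adjusted over the list alone), with a median of -1.15. SQLE, squalene epoxidase, fell by 2.12 (SE 0.083) and CYP51A1, lanosterol demethylase, fell by 1.85 (SE 0.095), and the second CYP51A1 probe set fell by 1.65. IDI1, isopentenyl diphosphate isomerase, rose 2.91-fold (SE 0.081 on the log2 scale) and SREBF2, the gene of the sterol-sensing transcription factor, 1.21-fold. Ribosome biogenesis genes and MYC fell in 10 of 13 and rose in 1 (the same when adjusted over the list alone), with log2 fold changes of -1.74 (SE 0.086) for NOLC1 and -1.68 (SE 0.11) for DKC1, the pseudouridine synthase of small nucleolar particles, while the RNA polymerase I subunit gene POLR1A rose 2.45-fold. Camera's adjusted p was 0.00285 for the sterol list and 0.00163 for ribosome biogenesis. Neither held with an estimated correlation, where adjusted p = 0.239 with an estimated correlation for sterol synthesis and 0.402 for ribosome biogenesis.

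The remaining lists did not pass camera's test against other genes, although single members changed. Fry, which does not compare a list with other genes, also passed several of them, with adjusted p-values of 0.00155 for endoplasmic reticulum stress, 0.00812 for immediate early, 0.0105 for NF-kB, 0.0126 for mesenchymal, 0.0196 for glycolysis and 0.0224 for interferon genes. Of 17 amino acid response genes, 6 rose and 8 fell (7 and 8 when adjusted over the list alone; median -0.11, mean 0.027, camera direction down, adjusted p = 0.887). CHAC1, a glutathione-degrading enzyme gene, rose 4.82-fold and SLC7A11, the cystine transporter gene, fell by 1.42 (SE 0.11). Among 12 endoplasmic reticulum stress genes, 1 rose and 7 fell (1 and 7 when adjusted over the list alone; adjusted p = 0.0602, or 0.0361 with an intensity trend in the prior), with EDEM1 2.46-fold higher and the log2 fold change of the chaperone gene HSP90B1 at -1.29 (SE 0.083). Among 17 interferon-stimulated genes, 7 rose and 1 fell (7 and 1 when adjusted over the list alone; adjusted p = 0.0788). IFIT3 rose 4.44-fold and IFIH1, the RNA sensor MDA5, 3.81-fold, whereas ISG15 had a log2 fold change of -0.075 (SE 0.091) and IFIT1 one of 0.020 (SE 0.14). Of 14 NF-kB and inflammatory genes, 3 rose and 6 fell (3 and 6 when adjusted over the list alone; adjusted p = 0.472). PTGS2, an inducible cyclooxygenase gene, rose 2.46-fold and the adhesion molecule gene ICAM1 fell by 1.22 (SE 0.081). Of 12 NRF2 antioxidant genes, 4 rose and 5 fell (4 and 6 when adjusted over the list alone; median -0.15, mean 0.038, camera direction up, adjusted p = 0.987). AKR1B10 rose 2.11-fold, from 4.575 to 5.655 log2 units, both under the medians of the 20 marker genes (6.26 uninduced, 6.34 induced). SRXN1 fell by 1.08 (SE 0.097). Of 14 glycolysis and hypoxia genes, 3 rose and 8 fell (3 and 8 when adjusted over the list alone; adjusted p = 0.152). The hexokinase gene HK2 fell by 1.27 (SE 0.11) and the phosphofructokinase gene PFKP fell by 1.08 (SE 0.085).

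Of 13 immediate early and heat shock genes, 5 rose and 5 fell (5 and 6 when adjusted over the list alone; camera adjusted p = 0.623). EGR1 and NR4A1, transcription factor genes of the immediate early response, rose 6.75-fold and 4.87-fold. Of 18 mesenchymal and matrix genes, 5 rose and 4 fell (6 and 4 when adjusted over the list alone; adjusted p = 0.623). ACTA2, smooth muscle actin, rose 14.1-fold, and ZEB2 fell by 1.48 (SE 0.15), while its second probe set fell by 0.79. Genes often used as references did not all hold level: of 10, 4 rose and 4 fell (5 and 4 when adjusted over the list alone; adjusted p = 0.708). HPRT1 fell 3.02-fold (SE 0.10 on the log2 scale) and B2M rose 1.67-fold, while GAPDH had a log2 fold change of -0.085 (SE 0.081, adjusted p = 0.467 in limma's test).

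Few markers of other cell types passed the test. Of 9 blood cell markers, 1 passed the test (0 when adjusted over the list alone), CD3E, with a log2 fold change of 0.26 (SE 0.081). CD68 had one of 0.18 (SE 0.085), and was bright in both groups, at 11.74 log2 units uninduced and 11.92 induced. Of 11 fibroblast and endothelial markers, 0 passed limma's test, adjusted over all genes or over the list alone, and 0 had an unadjusted p under 0.05. The largest differences in that list were 0.20 (SE 0.085) for CDH5 and 0.19 (SE 0.090) for VWF. Of 10 markers of differentiated lung epithelium, 2 rose (1 when adjusted over the list alone): SCGB1A1, the club cell secretoglobin, 4.08-fold and SFTPC 1.23-fold. Camera's adjusted p for these lists was 0.708, 0.623 and 0.163. The calls of CD3E and SFTPC ended when any array was left out and with an intensity trend in the prior.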

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

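These counts were made after the main results had been seen. Signals also appeared in rows of the table that the comparisons above do not use, and no explanation for them was weighed. Among 1754 probe sets assigned to several genes, 105 were at least 2-fold higher and 119 at least 2-fold lower on the induced arrays at an adjusted p under 0.05 in limma's test over all rows, with log2 fold changes from -3.92 to 4.29. Among 12083 probe sets without a gene symbol in the annotation, 222 were at least 2-fold higher and 446 at least 2-fold lower, with the largest rise at 5.48. Named and unnamed rows were called at different rates, 39.5% of those with 1 gene symbol, 36.3% of those with several and 20.2% of those with none, and the unnamed rows were dimmer, with a median level of 6.40 against 7.73 for rows with 1 symbol. Groups of 2 arrays are too small to look for outlying samples.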

How the results depend on the processing

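All alternatives were planned before the data were examined. No list and no gene named by the rule that was called, here or under an alternative, changed direction. Of the values of genes named by the rule, 797 kept their side of the threshold under the alternatives. Another 10 lost the call, all of CD3E or SFTPC, and 5 gained one, of MIR22HG, CDH5 or CD68. Genes named after their values were seen were not followed singly under the alternatives. The count of called genes was lower without any 1 array, most so without an uninduced one: leaving out each array in turn gave 4959 to 6904 genes, 2316 to 3119 higher and 2643 to 3785 lower, where the lone array left in a group is assumed to vary like the other group. The test against a fold of 1.2 called 5479 genes, 2502 higher and 2977 lower, since it asks for a larger change. With every probe set tested, named or not, 1871 were at least 2-fold lower. Rows without a gene symbol, which are among those this setting adds, held 446 falls and 222 rises of that size. The 2-fold count was otherwise 2285 to 2519, and under each setting at least 2282 of those genes were among the 2439 reported. The share of higher genes among all calls moved from 45.6% to 50.2% with quantile normalization again and 51.1% with median centring, and among 2-fold calls from 48.9% to 52.9% and 53.4% in that order. These scalings moved the median gene by 0.035 and 0.050 on the log2 scale. With camera's estimated correlation the adjusted p was 0.153 for growth arrest, apoptosis, metabolism, membrane and G1/S genes, 0.185 for feedback, 0.239 for DNA repair, 0.202 for G2/M and 0.272 for noncoding RNA, in a test with 2 residual degrees of freedom. The noncoding list of 3 genes also lost its call without dim probe sets (0.123), which tests fewer genes, and ranged from 0.0172 to 0.0587 when single arrays were left out (0.0172 to 0.272 over all alternatives). The endoplasmic reticulum stress list gained a call under an intensity trend (0.0361), with the replicate block (0.0359) and without uninduced array 1 (0.0405) or induced array 2 (0.0333), over a range of 0.0333 to 0.306. The interferon list gained one without uninduced array 1 (0.0405, range 0.0405 to 0.447), as did the lung epithelial list without induced array 2 (0.0324, range 0.0324 to 0.803). The causes of these gains were not tested. The groups share only replicate numbers: same-numbered arrays deviated together with a correlation of 0.22 across genes, over 2 pairs, and the fit with the replicate block called 7820 genes, 2437 of them at 2-fold. The background correction could not be varied on summarised values. The number of arrays and the dim end of the scale limit what could be detected.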

Other observations

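The gene families, the neighbour test, the airway cell lists and the sterol tests reported here were chosen after the main results had been seen. Of 22 families of protein-coding genes picked by symbol, 7 passed camera's test as lower, and their members partly overlap the cell cycle lists. None of these calls held with an estimated correlation, where adjusted p = 0.599 for nucleoporins and tubulins and 0.538 for the other 5. Of 18 centromere protein genes, 17 fell and 1 rose (median log2 fold change -1.87, camera adjusted p = 4.6e-08). Of 22 nucleoporin genes, 19 fell, with log2 fold changes of -2.46 for NUP35 and -2.31 for NUP107, and 1 rose (median -1.02, adjusted p = 4.2e-07). Of 31 splicing factor genes of the SR and hnRNP families, 20 fell and 1 rose, led by SRSF7, which fell by 1.78 (median -0.55, adjusted p = 1.5e-05). DNA polymerase genes fell in 14 of 19 and rose in 3 (POLE2 at -2.92, adjusted p = 0.000455), and Fanconi anaemia genes fell in 7 of 9 (FANCI at -2.92, adjusted p = 0.000455). Mitochondrial ribosomal protein genes fell in 39 of 73 and rose in 6 (median -0.28, adjusted p = 0.000931), and tubulin genes fell in 8 of 17 and rose in 1 (adjusted p = 0.0285). Cytosolic ribosomal protein genes, paralogs left out, rose in 7 and fell in 3 of 55 (adjusted p = 0.748), and the other 14 families did not pass camera's test either.

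Single members of families that did not shift also changed. CASP6 rose most of the 9 caspase genes (log2 fold change 3.27, SE 0.081), while CASP2 fell by 1.63 (SE 0.086). Among 12 voltage-gated sodium channel genes, SCN2A (3.35, SE 0.096) and SCN3B (3.17, SE 0.10) rose, 1 fell and 9 did not pass the test. SCN2A started at 4.68 log2 units, under the uninduced marker median of 6.26, so its change depends on the background level. Of 40 protocadherin genes 12 rose, 12 fell and 16 did not pass the test: PCDHB12, PCDHB11 and PCDHB3 rose by 2.38, 2.10 and 2.05, while PCDHB5 fell by 1.10. Outside these families, SLIT2 rose by 4.10 (SE 0.10) and the probe set of MIR218-1 by 3.82 (SE 0.095). Whether these probe sets read separate transcripts was not tested. At ACTA2 neighbouring genes diverged, since ACTA2 rose by 3.82 and FAS by 1.13 while STAMBPL1, on the other side of ACTA2, fell by 2.66. The spans of ACTA2 and FAS overlap, and whether the probe sets of ACTA2 and FAS read separate transcripts was not tested either.

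Measured protein-coding genes next to each other in gene order changed together more often than in shuffled gene orders. Genes that were not measured or not protein-coding were skipped, and no limit was set on the distance between neighbours. Among 16879 neighbouring pairs of protein-coding genes, 124 had both members at least 2-fold higher, against 77.6 on average over 10000 shuffles, and 146 had both lower, against 83.4. Overlapping transcripts cannot account for all of the joint rises, since 106 pairs whose spans do not overlap remained against 70.4. The two-sided permutation p was 0.0002, the smallest these shuffles can give. With pairs sharing the first 3 letters of their symbols also left out, 90 pairs of unlike symbols remained against 63.3 (permutation p = 0.0004). Probe sets of related genes are not excluded by this, since probe sequences were not compared. Related genes can have unlike symbols, such as H2BC11 and H2AC11, a pair that remained. Clustering of expressed genes takes part of the excess: among genes of like level those 90 pairs stood against 72.0 (permutation p = 0.0316). Joint falls of pairs chosen the same way kept an excess among genes of like level, 111 against 76.5 (permutation p = 0.0002). Pairs that moved in opposite directions were not in excess there, 152 against 148.1 (permutation p = 0.77), and shared regulation of neighbours is a candidate explanation that was not tested.

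Some rises were in genes known from airway cells, SCGB1A1 of club cells and CCDC39 and DNAI3 of cilia. The design already makes such cells unlikely, since all arrays were of the same cultured carcinoma line. Club cells would bring their other secretory transcripts, yet the upper quartile of log2 fold change over 9 other club and secretory markers was 0.085, and 0 of them passed limma's test (1 at an unadjusted p under 0.05), with SCGB3A1, the brightest on the induced arrays, at 7.31 uninduced and 7.53 induced. Ciliated cells are likewise argued against by 13 ciliated markers, of which FOXJ1 is also in the lung epithelial list: their upper quartile was 0.10, CAPS, the brightest, went from 8.74 to 8.92, and the one called, DNAH5, fell by 0.85. Among 63 axonemal dynein and CFAP genes, however, 8 rose, CFAP300 by 3.06 and CFAP77 by 1.29 besides DNAI3, and 11 fell (camera adjusted p = 0.748). A response of these single genes to p53 or to doxycycline stays open and may be read only as a hypothesis.

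For the fall of sterol synthesis genes, array scaling is argued against, since a scaling error moves genes of like level alike. The list's median log2 fold change was -1.15, whereas the 2.5th percentile of random lists matched on mean level was -0.56. The list was followed up because it had fallen in the main results, so these values are not a separate test. Doxycycline itself, without p53, cannot be told apart from p53 for this list (median -1.15), because no sample had the drug without the construct, and slower growth of the induced cells was not tested.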
